A study of Homo sapiens with 2 samples.

How the data were processed

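Poly(A)-selected RNA of P493-6 cells was sequenced from 1 low c-Myc sample (0 h after release of the repressed transgene) and 1 high c-Myc sample (24 h). Per the labels' protocols, total RNA was extracted, synthetic RNAs of the ERCC ExFold kit were added according to cell number, polyadenylated RNA was selected and fragmented, and libraries were made by a dUTP method that keeps the strand and amplified with 15 PCR cycles. Per the submitters' processing notes, Bowtie was used, with no version given, and the genome build was hg18. The counting tool, the filters, the treatment of reads with several matches and the use of strand in counting are not given in the sources used here. Reads from overlapping, antisense and near-identical genes therefore cannot be told apart.

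The authors deposited 1 table per library with RPKM values (reads per kilobase of transcript, scaled to the reads of the library), per the file headers, for RefSeq transcripts and synthetic RNAs. Which reads that scaling covers, and whether they include those of the synthetic RNAs, is not given in the sources used here. Per the file headers the authors also deposited an RPKM column renormalized to the synthetic RNAs, by a method not given in the sources used here, which was used only as an alternative. Both tables held 34286 rows, of which 92 were synthetic RNAs and 34194 were transcripts with 19096 gene symbols and 32783 accessions, and 1411 transcript rows repeated an accession. Symbols of 61 rows were listed as dates in place of names, and those genes were kept under the symbols as listed. Of the transcript rows, 8527 were at 0 in the low c-Myc library, 9639 in the high c-Myc library and 7993 in both. The tables give no positions, and no coordinates were used.

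Each gene symbol was represented by its row with the highest mean RPKM over both libraries. Expressed genes were the 10272 with a mean RPKM of at least 1. Ratios of high over low c-Myc were taken on the log2(RPKM + 0.5) scale, which understates differences of weakly expressed genes on the deposited scale. Per-cell log2 ratios were obtained by subtracting the median log2 ratio of the 46 synthetic RNAs with an RPKM of at least 1 in both libraries, with a bootstrap of 10000 draws over the synthetic RNAs. The pseudocount was added before that subtraction. Per cell it therefore draws weakly expressed genes towards the inverse of the synthetic RNA ratio, not towards 0. A gene was called higher or lower by a fixed rule of size, a log2 ratio at or beyond 1 or -1. RPKM values are not counts and each group had 1 library, so no count model was used and no p-value is given.

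The depth of each library was taken from the low values. RPKM times transcript length fell on steps that implied about 103000000 reads for the low c-Myc library and 106000000 for the high one. Of 3250 and 2322 transcripts with up to 20 reads by that measure, 48.5% and 44.5% lay within 0.05 of a whole number, against 10% by chance, and the ratio of depths was 1.02 both from lengths and from the commonest ratio of low values. Approximate reads per gene were RPKM times length times that depth, and exact binomial intervals at 95% on them cover counting error only, since PCR copies are not independent molecules. Transcript length and GC content came from GENCODE release 29 transcripts paired by RefSeq accession, which gave a value for 9949 (96.9%) of the expressed genes. These lengths are not those of the annotation the authors used, so reads per gene are approximate.

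The 35 gene lists were fixed before the data were examined, and all of their 876 members were found in the tables. They covered the MYC network, ribosome biogenesis, ribosomal proteins, translation factors, tRNA synthetases, nucleotide and polyamine synthesis, one-carbon metabolism and amino acid uptake, glycolysis, the respiratory chain, mitochondrial import, protein folding, the proteasome, nuclear transport and splicing, S phase entry, mitosis, growth arrest, apoptosis, B cell identity, plasma cells, MHC class I and class II, NF-kB activation, the interferon response, immediate early genes, cholesterol synthesis, lysosomes, stress responses, RNA polymerase II, histones, reference genes, and markers of T cells, NK cells, myeloid cells, erythroid cells and platelets, and fibroblasts and epithelium. For the 32 lists with at least 3 measured members, the percentile of the median was taken among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these libraries. The genes named were chosen by a rule also fixed then, which takes MYC and its network, the 12 highest and 12 lowest log2 ratios, the 2 highest and 2 lowest measured members of each list, and other cell types' markers at an RPKM of at least 1. Values of some single genes that this rule takes are not reported here.

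Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The procedure was tested on simulated libraries with 10283 expressed genes and a synthetic RNA ratio of -2.5 on the log2 scale. For high over low c-Myc, all 50 genes planted at a log2 ratio of -3, 48 of 50 at -1.5, 49 of 50 at 1.5 and all 50 at 3 passed the threshold, none of 10083 unchanged genes did, and the synthetic RNA ratio was recovered as -2.45. The simulated noise between libraries was a small value set by choice, and no GC trend was planted. These counts therefore check the calculation and give no error rate for the real libraries. Alternatives planned beforehand were other pseudocounts, filters, thresholds and treatments of symbols with several rows, other summaries of the synthetic RNAs, centring, quantile normalization, other bins for the random lists and means in place of medians. The authors' renormalized columns, a correction for GC content and scaling to the same RPKM sum without the synthetic RNAs were added after the data had been seen. The GC correction subtracted a loess curve of the log2 ratio on transcript GC content and kept the overall median.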

Results

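RNA sequencing was analysed from P493-6 cells, a human B cell line in which tetracycline holds a c-Myc transgene silent. c-Myc is a transcription factor that binds the promoters of many active genes and drives cell growth and division. The low c-Myc group held 1 library, from cells taken 0 h after repression was lifted, and the high c-Myc group held 1 library, from cells taken 24 h after it. With 1 library per group, no difference had a replicate check, no test between the conditions was made, and every value describes this pair of libraries. Synthetic RNAs of known sequence were added to each sample by cell number, so each gene could be compared on the deposited RPKM scale and, after division by the ratio of the synthetic RNAs, per cell. The steps between the lowest RPKM values implied about 103000000 reads in the low c-Myc library and 106000000 in the high c-Myc library, so that a 2 kb transcript at an RPKM of 1 rested on about 206 and 211 reads.

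The 92 synthetic RNAs took 17.5% of the summed RPKM of the low c-Myc library and 2.75% of that of the high c-Myc library. Among the 46 synthetic RNAs at an RPKM of 1 or more in both libraries, the median log2 ratio of high over low was -2.56 (interquartile range -2.84 to -2.17, SD 0.54 over the synthetic RNAs). Their RPKM was thus a median of 5.88-fold higher in the low c-Myc library, with a 95% bootstrap interval of 5.38 to 6.52 that covers only the spread between synthetic RNAs. A similar number of genes was detected in each library at an RPKM of 1 or more, with 10036 genes in the low c-Myc library, 10112 in the high c-Myc library and 9581 in both.

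MYC itself was already abundant before release and higher after it. The MYC transcript (NM_002467) stood at an RPKM of 836 in the low c-Myc library, where it ranked 18 of the 10272 expressed genes, and at 2358 in the high c-Myc library, where it ranked 3. That is a 2.82-fold higher level on the deposited scale (log2 ratio 1.496, 95% counting interval 1.489 to 1.503) and a 16.6-fold higher level per cell. Of the 9 measured genes of the MYC network, MYC, MNT and MXI1 were at least 2-fold higher on the deposited scale, none was 2-fold lower, and the list's median log2 ratio was 0.42. MNT, a repressor that competes with MYC for its partner MAX, had a log2 ratio of 1.68, while MAX stood at an RPKM of 46.6 in the low c-Myc library and 47.4 in the high one. The deposited values do not separate reads of the transgene from reads of the endogenous MYC gene.

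On the deposited scale the first comparison asked which transcripts had a higher or lower RPKM after c-Myc was released. At least 2-fold higher in the high c-Myc library were 52 of 57 ribosome assembly genes and 25 of 28 genes of nucleotide and polyamine synthesis. So were 12 of 18 genes of one-carbon metabolism, serine synthesis and amino acid uptake. The same held for 21 of 27 genes of mitochondrial import, chaperones and genome maintenance and 32 of 42 of S phase entry and DNA replication. At least 2-fold lower were 10 of 16 immediate early genes, 16 of 26 interferon response genes, 10 of 15 MHC class II genes and 13 of 30 B cell genes. MIF, a secreted cytokine (NM_002415), had the highest log2 ratio with the pseudocount of 0.5, at 5.52, with an RPKM of 25.6 in the low c-Myc library and 1200 in the high one. Without a pseudocount several genes, among them NPW (8.39), DDN (7.06), LRP3 (6.89) and TERT (6.67), exceeded MIF (5.55), and after a correction for transcript GC content so did DDN (4.76), HPDL (4.58), NME1 (4.19) and RRS1 (4.17) among the named genes (MIF 4.11). FOS, an immediate early transcription factor (NM_005252), had the lowest at -6.29, with an RPKM of 424 in the low c-Myc library and 4.92 in the high one. Of the 10272 expressed genes, 2554 were at least 2-fold higher, 1001 were at least 2-fold lower and 6717 lay between, around a median log2 ratio of 0.22 (interquartile range over genes -0.44 to 0.997). Centring the ratios on that median gave 2036 higher and 1516 lower genes, so the share of higher genes among those past 2-fold was 71.8% as deposited and 57.3% after centring. Scaling to the same RPKM sum without the synthetic RNAs gave 1867 higher and 1642 lower genes (53.2% higher) around a median of -0.07, and quantile normalization gave 1777 and 1768 (50.1%).

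**Figure D1:**
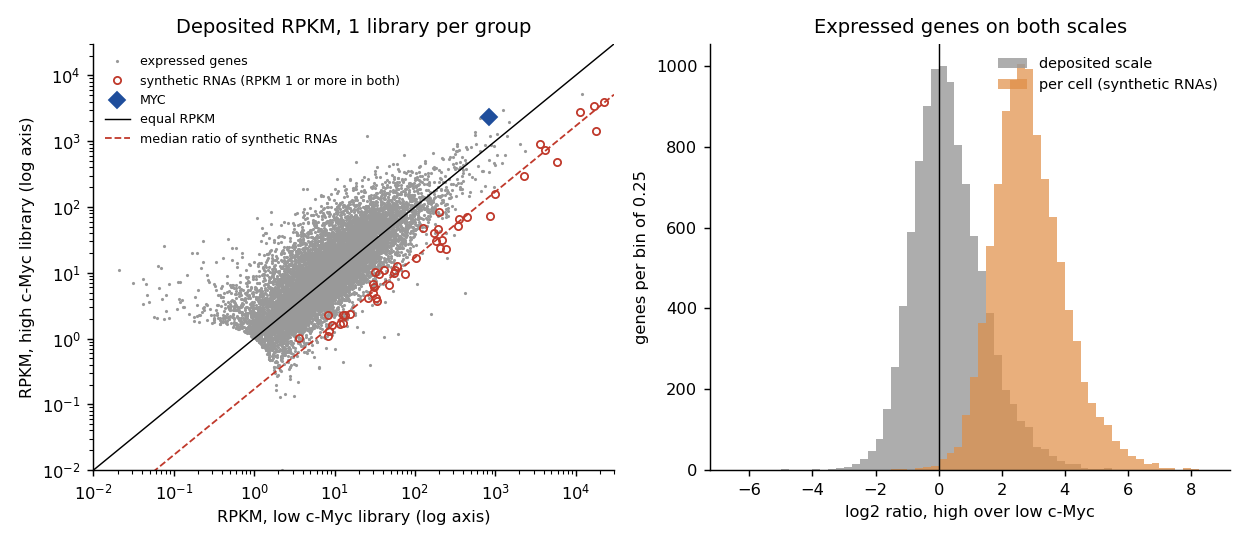
Left, RPKM of each expressed gene (grey), of the 46 synthetic RNAs at an RPKM of 1 or more in both libraries (red circles) and of MYC (blue) in the low c-Myc library (x axis) and the high c-Myc library (y axis), both on log axes, with values under 0.01 drawn at 0.01. Right, log2 ratios of the 10272 expressed genes, whose median is 0.22 on the deposited scale (grey) and 2.78 per cell (orange).

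The 12 genes with the highest ratios also included HPDL, RAC3, MATK, CCDC85B, COMTD1, LRP3, NPW and DDN. TERT, the catalytic subunit of telomerase, had a log2 ratio of 4.87 and an RPKM of 0.19 in the low c-Myc library against 19.7 in the high one. SLC19A1, the reduced folate carrier, had a log2 ratio of 4.71, and JAG2, a Notch ligand, one of 4.79. The 12 genes with the lowest ratios included EGR1 at -5.83, the lymphocyte activation marker CD69 at -5.22, the G protein signalling regulator RGS2 at -4.99 and the cytokine signalling inhibitor SOCS3 at -4.76. SAT1, which starts polyamine breakdown, stood at an RPKM of 107 in the low c-Myc library and 6.74 in the high one, a log2 ratio of -3.89. The nuclear receptors NR4A1 and NR4A2, FOSB, YPEL5, the glucose transporter SLC2A3 and the phosphatase DUSP5 made up the rest of that end.

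Ribosome assembly genes had the highest median of the 32 lists with at least 3 measured genes. Of the 57 measured genes of the nucleolus and ribosome biogenesis, 52 were at least 2-fold higher and none was 2-fold lower, with a median log2 ratio of 2.25, above the medians of all 10000 random lists of the same size matched on mean expression. BOP1 and RRS1, both needed to build the large ribosomal subunit, had log2 ratios of 4.42 and 4.34, while NOP10 stood at -0.12. Of the 77 cytoplasmic ribosomal proteins, 29 were higher, 3 lower and 45 between, with a median of 0.39 at percentile 57.9 of the random lists. RPS15 had a log2 ratio of 2.62 and RPL11 one of -1.17, although ribosomal protein genes have many near-identical copies and their values are uncertain. Among 35 translation factors, 17 were higher and none lower, with a median of 0.91 at percentile 97.1 (98.8 for the mean and 99.7 after the GC correction), and EIF4EBP1, an inhibitor of cap-dependent initiation, had a log2 ratio of 2.85. Among 20 aminoacyl-tRNA synthetases, 9 were higher and none lower, with a median of 0.85 at percentile 85.9 and VARS at 3.19.

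The next highest medians were those of nucleotide and polyamine synthesis and of the list of one-carbon metabolism, serine synthesis and amino acid uptake. Of 28 genes of purine, pyrimidine and polyamine synthesis, 25 were higher and none lower, with a median of 2.14 above all random lists. SRM, which makes spermidine, stood at an RPKM of 18.6 in the low c-Myc library and 484 in the high one, a log2 ratio of 4.67, and NME1, whose reads can overlap those of NME2, had a log2 ratio of 4.16. Of 18 genes of one-carbon metabolism, serine synthesis and amino acid uptake, 12 were higher and 1 was lower, with a median of 2.07 above all random lists. SLC7A5, a carrier of large neutral amino acids, had a log2 ratio of 4.25, and SLC38A2, another amino acid transporter, was the lower gene at -1.62. Of 20 glycolysis genes, 11 were higher and 1 was lower, with a median of 1.19 at percentile 97.9, which was 81.0 for the mean in place of the median and 94.8 after the GC correction. The lactate transporter SLC16A1 had a log2 ratio of 3.14, and SLC2A3 was the lower gene at -3.27. Of 23 cholesterol synthesis genes, 9 were higher and none lower, with a median of 0.52 at percentile 65.1.

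Many mitochondrial and protein folding genes were also higher in the high c-Myc library. Of 27 genes of mitochondrial import, chaperones and genome maintenance, 21 were higher and none lower, with a median of 1.76 above all random lists. POLRMT, the mitochondrial RNA polymerase, had a log2 ratio of 3.65 and the prohibitin gene PHB one of 3.61. Of 45 nuclear-encoded respiratory chain genes, 21 were higher and none lower, with a median of 0.93 at percentile 96.8 (99.85 for the mean and 99.99 after the GC correction), and ATP5D had a log2 ratio of 3.54 while NDUFA4 stood at -0.75. Of 20 chaperonin and folding genes, 13 were higher and none lower, with a median of 1.46 at percentile 99.6, and PFDN2 had a log2 ratio of 2.95. Of 31 proteasome subunits, 9 were higher and none lower, with a median of 0.67 at percentile 71.4. Of 34 genes of nuclear transport and splicing, 20 were higher and none lower, with a median of 1.19 at percentile 99.8, and the importin IPO4 had a log2 ratio of 3.27.

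Most replication genes were higher in the high c-Myc library and several growth arrest genes were lower. Of 42 genes of S phase entry and DNA replication, 32 were higher and none lower, with a median of 1.68 above all random lists. UHRF1, which maintains DNA methylation, had a log2 ratio of 3.77 and UNG, a uracil DNA glycosylase, one of 3.72, while CCND2 stood at -0.21. Of 27 genes of G2 and mitosis, 10 were higher and none lower, with a median of 0.66 at percentile 98.5, CCNA2 at 2.57 and HMMR at -0.76. Of 18 measured cyclin-dependent kinase inhibitors and growth arrest genes, 8 were lower and 1 was higher, with a median of -0.76 at percentile 0.01. TXNIP, a thioredoxin inhibitor, had a log2 ratio of -2.999 and the antiproliferative gene BTG1 one of -2.11, and CDKN2A was the higher gene at 2.53. Of 12 replication-dependent histone genes, 4 were lower and none higher, with a median of -0.91 at percentile 0.06, although most histone transcripts lack the poly(A) tail on which the libraries were selected.

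Many genes of B cell identity and MHC class II presentation were lower in the high c-Myc library on this scale, while MHC class I genes lay on both sides of 0. Of 30 B cell identity and B cell receptor genes, 13 were lower and none higher, with a median of -0.93, below all random lists. MS4A1, which encodes CD20, stood at an RPKM of 962 in the low c-Myc library and 204 in the high one, a log2 ratio of -2.23, and CD72 had one of -2.27, while IKZF1 stood at -0.04. Of 15 MHC class II presentation genes, 10 were lower and none higher, with a median of -1.09, below all random lists, and HLA-DOB, which like other HLA genes can share reads with near-identical relatives, had a log2 ratio of -1.36 while the class II transactivator CIITA stood at 0.07. Of 16 MHC class I presentation genes, 3 were lower and 2 were higher, with a median of -0.02 at percentile 9, which was 2.11 for the mean and 25.9 after the GC correction. B2M, the class I light chain, had a log2 ratio of -1.76. Of 10 plasma cell genes, 1 was higher and 1 lower, with a median of 0.35 at percentile 51.3, SDC1 at 1.97 and the joining chain gene IGJ at -1.79.

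Immediate early and interferon response genes had the lowest medians among the lists of 10 or more measured genes. Of 16 immediate early genes, 10 were lower and 1 was higher, with a median of -1.75, below all random lists. The higher gene was JUND, with a log2 ratio of 1.38 that was -0.50 after the GC correction. Of 26 type I interferon response genes, 16 were lower and none higher, with a median of -1.19, below all random lists, IFIT2 at -2.57 and IFI44L at -2.39, while ISG15 stood at an RPKM of 1479 in the low c-Myc library and 1983 in the high one, a log2 ratio of 0.42 that was -0.62 after the GC correction. Of 26 lysosome and autophagy genes, 4 were lower and 2 higher, with a median of -0.18 at percentile 2.73, which was 0.61 for the mean. Of 25 genes of NF-kB and EBV-associated activation, 1 was lower and 3 were higher, with a median of -0.06 and a mean of 0.01, at percentile 7.13, and after the GC correction the median was 0.04 at percentile 24.1. Of 23 apoptosis regulators, 3 were higher and 1 was lower, with a median of -0.04 at percentile 10.3, and BBC3, which encodes the death-promoting protein PUMA, had a log2 ratio of 2.15 against -2.25 for CASP8. Of 17 genes of the unfolded protein and integrated stress responses, 5 were higher and 1 was lower, with a median of 0.44 at percentile 53.5.

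**Figure D2:**
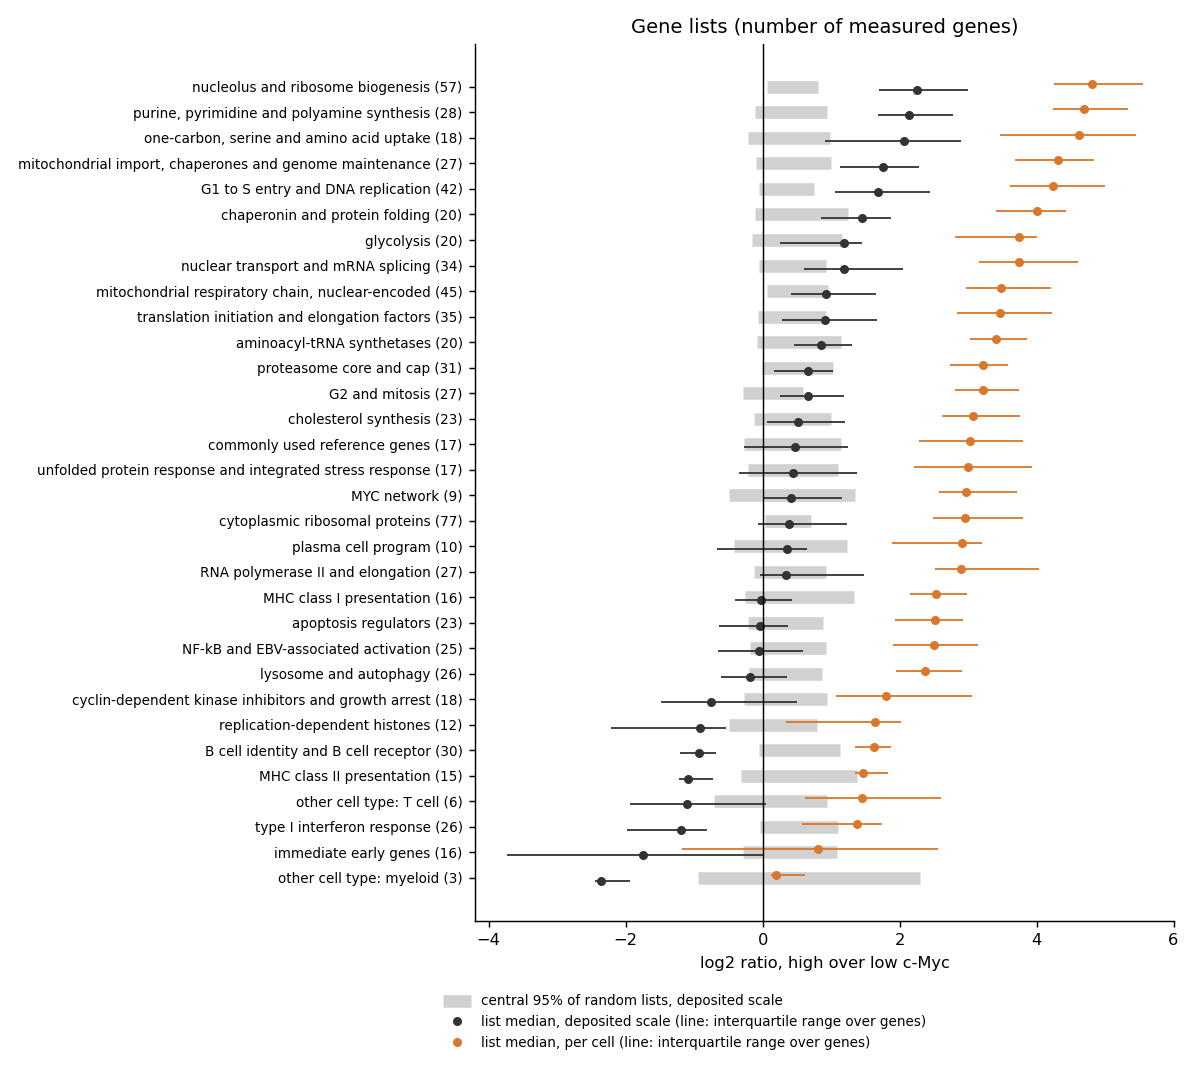
Median log2 ratio of high over low c-Myc (x axis) for the 32 gene lists with at least 3 measured genes, on the deposited scale (black) and per cell (orange), with lines for the interquartile range over genes and grey bars for the central 95% of 10000 random lists on the deposited scale. The nucleolus and ribosome biogenesis list lies at 2.25 on the deposited scale and the type I interferon list at -1.19, and both lie above 0 per cell.

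Genes often used as references differed among themselves. Of 17 such genes, 5 were higher and 1 was lower on the deposited scale, with a median of 0.47 at percentile 58.5, and TUBA1B and HPRT1 had log2 ratios of 1.86 and 1.82 against -1.76 for B2M. Of 27 genes of RNA polymerase II and elongation, 8 were higher and none lower, with a median of 0.34 at percentile 46.7 and POLR2I at 2.66. Quantile normalization turned the sign of 4 list medians, those of the MYC network, the plasma cell genes, the RNA polymerase II genes and the unfolded protein response genes, and neither centring nor scaling to the same RPKM sum without the synthetic RNAs turned any.

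Several markers of other cell types were lower in the high c-Myc library, as the B cell genes were. The 3 measured myeloid genes were all lower in the high c-Myc library on the deposited scale, with a median log2 ratio of -2.36 at percentile 0.03, where CD68 stood at an RPKM of 66.5 and 11.1, LYZ at 27.2 and 4.91, and ITGAM at 56.8 and 19.5 in the low and high c-Myc libraries. Of 6 measured T cell genes, 3 were lower and none higher, with a median of -1.10 at percentile 0.17, and CD3E stood at an RPKM of 8.30 and 1.499. PRF1 was the 1 measured NK cell gene, with a log2 ratio of -0.81, PDGFRB and COL1A1 were the 2 measured fibroblast and epithelial genes, at -1.77 and 0.19, and no erythroid or platelet gene was measured.

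Ratios also went with the abundance and the GC content of the transcripts. The median deposited log2 ratio was 0.01 in the least abundant of 4 equal bins of expressed genes and 0.64 in the most abundant, a gap of 0.62 that was 0.086 after a correction for GC content. Across the 9949 expressed genes with a GC value, which are not independent replicates, Spearman's rho between the log2 ratio and GC content was 0.41. The median log2 ratio was -0.36 in the most AT-rich of 10 equal bins and 1.38 in the most GC-rich, and the 12 genes with the highest ratios had a median GC content of 66.4% against 50.3% over all genes. After the correction 2125 genes were higher and 907 lower, of which 1811 and 651 were among the genes counted on the deposited scale. Corrected values cover only the 9949 genes with a GC value, while the deposited counts cover all 10272 expressed genes. The correction moved the percentile of the ribosomal proteins to 94.0, of the tRNA synthetases to 95.4, of the proteasome to 96.5, of cholesterol synthesis to 96.7, of the RNA polymerase II genes to 83.4, of the reference genes to 92.2 and of the apoptosis regulators to 17.1. It left smaller log2 ratios for several named genes, among them 1.72 for ATP5D, 1.62 for EIF4EBP1, 1.04 for MNT, 2.30 for POLRMT, 3.23 for BOP1, 3.69 for SRM and 3.51 for TERT.

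**Figure D3:**
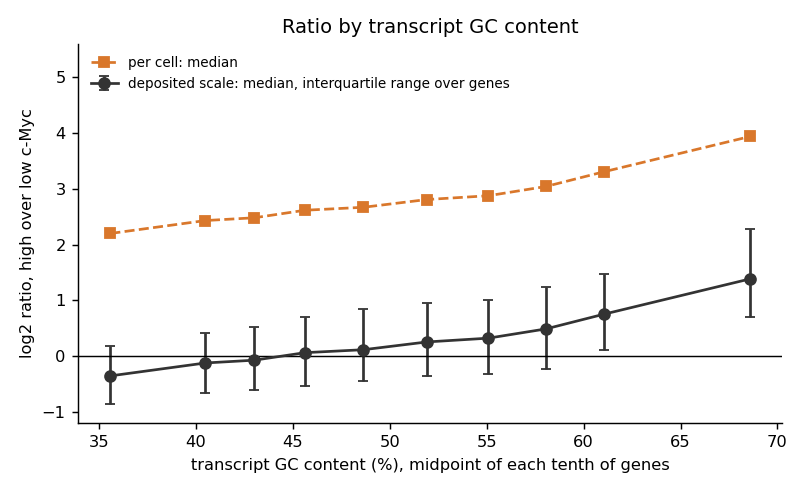
Median log2 ratio of high over low c-Myc (y axis) in 10 equal bins of expressed genes by transcript GC content in percent (x axis), on the deposited scale with the interquartile range over genes (black) and per cell (orange). The deposited median goes from -0.36 in the most AT-rich bin to 1.38 in the most GC-rich.

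The second comparison asked how transcript levels differed per cell, with the synthetic RNAs as the common measure. Nearly all expressed genes were higher per cell in the high c-Myc library, and the few lower genes included immediate early genes and the activation marker CD69. Of the 10272 expressed genes, 9976 (97.1%) were at least 2-fold higher, 9 were at least 2-fold lower and 287 lay between, around a median log2 ratio of 2.78, or 6.86-fold (interquartile range over genes 4.33-fold to 11.7-fold). The 9 lower genes were FOS, EGR1, CD69, RGS2, SOCS3, SAT1, NR4A1, NR4A2 and FOSB, with FOS 13.3-fold, EGR1 9.65-fold and CD69 6.34-fold higher in the low c-Myc library. On this scale 32 genes had a log2 ratio below 0, against 4248 on the deposited scale. These counts depend on the pseudocount, which draws weakly expressed genes towards the 5.88-fold ratio of the synthetic RNAs. Without it YPEL5 and SLC2A3 were also at least 2-fold lower, at 0.496-fold and 0.468-fold.

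Lists that were lower on the deposited scale had medians above 0 per cell. The B cell identity genes had a median of 3.08-fold, with 25 of 30 at least 2-fold higher and none lower, and MS4A1 at 1.25-fold. The MHC class II genes had a median of 2.76-fold, with all 15 higher, and the type I interferon genes one of 2.59-fold, with 16 of 26 higher and 10 between. The growth arrest genes had a median of 3.49-fold, with 14 of 18 higher, and TXNIP stood at a log2 ratio of -0.44. With the pseudocount of 0.5, the immediate early genes formed the only list with members at least 2-fold lower. They had 7 higher, 5 lower and 4 between, with a median of 1.75-fold. Without a pseudocount the glycolysis, NF-kB and T cell lists also held such members, among them SLC2A3 at 0.468-fold. A single factor was subtracted from every gene, so the order of the lists was the same on both scales, with medians of 28.1-fold for the nucleolus and ribosome biogenesis, 25.9-fold for nucleotide and polyamine synthesis, 24.7-fold for one-carbon metabolism and amino acid uptake, and 18.9-fold for S phase entry and replication. All 77 ribosomal proteins and all 27 RNA polymerase II and elongation genes were at least 2-fold higher, with medians of 7.72-fold and 7.43-fold.

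The size of the difference per cell went with abundance, from a median of 5.94-fold in the least abundant of the 4 bins to 9.14-fold in the most abundant, a log2 gap of 0.62 that was 0.086 after the GC correction and 1.10 with the authors' renormalized values. The scale rests on equal addition and recovery of the synthetic RNAs in 1 pair of samples, which these data do not check. With the authors' own renormalized values in place of the synthetic RNA ratio, 9244 genes were higher and 18 lower, and all 9 of the lower genes were among the 18. The pseudocount was added to those renormalized values, where it draws weakly expressed genes towards 0. The counts and the gap of 1.10 therefore differ from the main ones also in how the pseudocount acts.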

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

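All tests in this part were chosen after the results had been seen, except those of the listed genes and of transcript length against the GC trend.

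In the renormalized column of the high c-Myc library, some transcripts held values of 1 or more where the RPKM column held almost none. The renormalized column served only as an alternative in the comparisons. Of 2774 transcripts above 0 and below an RPKM of 0.1 in the high c-Myc library, 488 had a renormalized value of 1 or more. All 488 were among the 502 of these transcripts at 0 in the low c-Myc library. Those 502 had a median renormalized value of 5.82 in the high c-Myc library. The method of the renormalization is not given in the sources used here, so the cause was not tested. The largest such value was 18.5, for BEAN1, at an RPKM of 0.0989. The 7993 transcripts at 0 in both RPKM columns held 0.00750 in the renormalized column of the high c-Myc library and 0 in that of the low one.

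The log2 ratios went up with transcript GC content, with a Spearman's rho of 0.41 across genes. The trend did not rest on the listed genes alone, since rho was 0.432 over the 9178 expressed genes that have a GC value and are in no list. Growth-related genes outside the lists remain among those 9178, so their part in the trend was not tested. Transcript length does not account for the trend, since the lowest rho within 4 bins of length was 0.373. A difference between the libraries in the yield of GC-rich fragments may contribute, since such a difference would also act among subunits of 1 complex, where rho was 0.615 for the respiratory chain, 0.521 for the proteasome and 0.294 for the ribosomal proteins. The lowest of these lies just under the bound of 0.3 set for that test. A preference of the response for GC-rich genes could also act within a complex, so these values cannot separate it from a technical trend. The GC content of the synthetic RNAs, which come from no cell, was not set against their ratios. The trend bears on MIF, TERT and the other genes with the highest ratios, whose GC contents lay between 61.6% and 73.4%.

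MYC ranked 18 of the 10272 expressed genes in the low c-Myc library, at 35.4% of its RPKM in the high one. RNA of high c-Myc cells mixed into the low c-Myc sample would raise all other genes to at least a like share, but 588 genes had a low-to-high ratio under 17.7%, and MIF stood at 2.13%. Incomplete repression of the transgene and reads from the endogenous gene remain candidate explanations that cannot be told apart, because the tables give 1 MYC transcript and no value of the transgene alone.

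The synthetic RNAs differed in their ratio between the libraries even where they were abundant, from -3.65 to -1.97 on the log2 scale among the 9 at an RPKM of 100 or more in both. Counting noise does not account for this, since the SD among these 9 was 1.59 times that among 20 less abundant ones. Those 20 had an RPKM from 1 to under 10 in the library where they were lower. The use of different formulations of the kit, in which some RNAs differ 4-fold from others, would part the ratios into groups, and among the 26 at an RPKM of 10 or more the largest gap between neighbouring ratios was 0.317. Among the 9 alone, a set too small to tell groups from scatter, it was 0.653. These gaps leave the use of different formulations open, since scatter with an SD of 0.63 among the 26 could blur such groups. No biological explanation was tested for these RNAs, which come from no cell.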

How the results depend on the processing

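Among the alternatives, those with the authors' renormalized columns, the GC correction and the same RPKM sum without the synthetic RNAs were chosen after the data had been seen, and the causes of the differences were not tested except where the alternative's construction sets them. No paired analysis was possible because each group held 1 library and no result came from a test. Under the alternatives, 79 values of the comparisons stayed within 1.5 times the count or within 0.54 on the log2 scale and 18 did not. The 0.54 is the SD between single synthetic RNAs and does not measure the error of a median over genes. Within it lay changes of the deposited median from 0.22 to -0.07 and of the per-cell gap between abundance bins from 0.62 to 1.10. That gap is counted on both scales, though most alternatives give it the same value on each. The median per cell stayed between 2.25 and 2.90 and the synthetic RNA ratio between -2.59 and -2.496. Genes lower per cell numbered 15 with a pseudocount of 0.1, 14 and 5 at thresholds of 0.5 and 2, and 18 with the authors' columns. On the deposited scale, thresholds of 0.5 and 2 gave 4065 and 807 higher and 2355 and 111 lower genes, and a mean RPKM of at least 5 gave 649 lower genes, as their construction sets. Keeping every row gave 4247 higher and 1960 lower on the deposited scale and 18160 higher per cell, counting transcripts in place of genes. Lower genes numbered 1516 after centring, 1768 after quantile normalization and 1642 with the same RPKM sum, which put the median of all genes at -0.07. An RPKM of at least 5 left 6491 genes detected in the low c-Myc library. The gap between the most and least abundant bins was 0.086 on either scale after the GC correction, which also turned JUND to -0.50. Among named genes, 186 values moved and 2589 did not. Against the outer 5% of random lists, glycolysis left with the mean (81.0) and the GC correction (94.8), while translation factors (98.8 and 99.7) and the respiratory chain (99.85 and 99.99) entered with both, MHC class I (2.11) and lysosome (0.61) with the mean, and lysosome (2.42) with 10 bins.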

Other observations

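Within several lists, genes not described so far differed between the libraries on the deposited scale. Among cholesterol synthesis genes, DHCR7, which makes cholesterol in a last step of the pathway, had a log2 ratio of 2.31. Among stress response genes, SDF2L1, an endoplasmic reticulum protein, had a log2 ratio of 2.91 that was 1.66 after the GC correction, and the pseudokinase gene TRIB3 one of 1.91, against -1.51 for the transcription factor gene DDIT3. Among lysosome and autophagy genes, MAP1LC3B, whose product coats autophagosomes, had a log2 ratio of -1.58, while the protease gene CTSD had one of 1.52 that was 0.52 after the GC correction. In the list of one-carbon metabolism, serine synthesis and amino acid uptake, ASS1 stood at an RPKM of 0.12 in the low c-Myc library. It stood at 7.17 in the high one, and it acts in arginine synthesis. Per cell, DDIT3 was 2.06-fold, MAP1LC3B 1.97-fold and DHCR7 29.1-fold higher in the high c-Myc library.

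At an RPKM of 1 or more, 455 genes were detected in the low c-Myc library alone and 531 in the high c-Myc library alone. These numbers were 354 and 314 at an RPKM of 0.1 or more, and 708 and 1120 at 5 or more. Which library had more thus depended on the cutoff, and a gene under it was not necessarily absent. With the high c-Myc library put on the scale of the low one through the synthetic RNAs, it held 11713 genes at an RPKM of 1 or more, against 10112 as deposited. Scaling that library up could only raise its count.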
